A study of Mus musculus with 6 samples.

How the data were processed

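Gene expression was measured on 2-colour whole-genome oligonucleotide arrays in mouse MMH cells, with Prox1 against empty vector cells on each array and the dyes swapped between 3 arrays and the other 3. Per the labels' protocols, RNA was isolated with a column kit (for replicate 4 with a phenol-based reagent), treated with DNase, copied to cDNA, amplified by PCR that was stopped before saturation, and labelled with Cy3 or Cy5. The PCR step can compress or distort ratios between transcripts. The authors deposited 1 value per feature and array, and this value is a score: a signed, log-like ratio of both channels, not centred on 0, whose SD over the features with a value was exactly 1 in each of the 6 columns. The scanner software, the background correction, the normalization and the scaling step are not given in the sources used here. The log base and the SD before scaling stay unknown, so no fold change can be recovered, and equal scores on different arrays need not be equal ratios. Signal intensities were not analysed here, so signal over background is unknown for every feature. The analysis planned for log2 ratios was run on these scores, and a planned threshold of a fold change was dropped.

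The table held 44290 features, of which 41230 had a value in all 6 columns and 3060 in none. Column medians were 0.060, 0.055 and 0.058 with Prox1 in Cy5 and −0.020 with Prox1 in Cy3, within the preset distance of 0 at which values were kept as deposited. The 3 columns with Prox1 in Cy3 differed in 0 features, although the labels list them as separate arrays and give replicate 4 another RNA isolation; they differ by less than any sampling noise and were counted as 1 sample. Whether that profile is 1 array or a mean of several is unknown. The planned rule of values on at least 2 arrays per orientation is met only when these columns are counted singly.

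The direction of the ratios is not stated. Columns of opposite dye orientation correlated positively over features (r = 0.397 to 0.444, against 0.915 to 0.930 among the arrays with Prox1 in Cy5; features are not independent replicates), so both orientations were already turned the same way. The Prox1 feature at rank 4 of 41230 makes Prox1 over vector the likely direction. Zeros were written with a minus sign in the columns with Prox1 in Cy5 and without one in the others, a trace of a sign change whose start is unknown, and with a Cy5 over Cy3 start it would give the opposite direction.

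Feature names came from a platform annotation of 2016 updated by gene identifier. Of the features with a value 31700 had 1 symbol, 47 several and 9483 none. Features with exactly 1 symbol were averaged per gene on each array (19087 genes, 8251 of them with more than 1 feature), and the rest stayed single, which gave 28617 features for testing. In 730 of the 8251 genes, features that passed the threshold singly went in both directions, so a gene mean can hide opposite features. The files name no genome build, and no coordinates are given.

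Each of the 4 profiles entered a limma model with an intercept, which is the effect of Prox1, and a dye term of opposite sign in each orientation. This model weights both orientations equally (limma 3.58.1, R 4.3.3; empirical Bayes moderation, 2 residual degrees of freedom, Benjamini-Hochberg adjustment over all features, threshold 0.05). The residual spread comes from the 3 arrays with Prox1 in Cy5 alone, and the lone profile of the other orientation is assumed to vary like them. A dye term cannot be told from any other difference between the orientations. For this reason a model with the orientation as a random block (duplicateCorrelation, consensus correlation 0.793) was added after the data were examined. The gene lists, 23 in all with 599 of their 645 members measured, were fixed before the data were examined and tested with camera at a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. All list p-values are two-sided. Median and mean had opposite signs for the G1 and S phase list (0.12 and −0.04, camera direction up) and the stellate cell and fibroblast list (0.01 and −0.07, camera direction down). With the correlation estimated from the data, which has few degrees of freedom here, 0 of the lists passed. Adjusted over the list alone, counts of members were close to those over all features: 17 falls and 0 rises in cholesterol synthesis, 22 and 2 in G2 and mitosis, 1 and 22 in ribosomal proteins, 16 and 5 in plasma proteins, 12 and 1 in bile acid and drug metabolism, 14 and 2 in fatty acid and glucose metabolism, 15 and 8 in liver transcription factors, 16 and 4 in cholangiocyte and progenitor markers, 17 and 8 in adhesion, and 4 and 12 in cell cycle inhibitors.

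The genes named in the results follow a rule fixed before the data were examined: the genes of the labels whatever their values, the 12 largest rises and 12 largest falls among genes that passed with 1 sign in every profile, and from each list up to 4 members with the smallest p; clone, predicted, olfactory and pseudogene symbols were passed over. This rule gave 116 genes. Another 17, from 3 lists added after the data were examined, were chosen after their values were seen. Effects are given as estimate ± SE in SD units.

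The alternatives planned were no dye term, centring, scaling to 1 median absolute deviation, quantile normalization, array weights, robust moderation, leaving out each replicate, each probe by itself, a stricter threshold of 0.01, and 2 other forms of the list test. Added after the data were examined were the random block, the orientations as 2 replicates, the identical columns as 3 arrays, and each orientation by itself. In data simulated for this comparison (28617 features, of which 200 had an effect of known size, real spreads, and the real orientation differences as dye effects), the model with a dye term recovered 4% of effects of 0.5 SD units, 50% of effects of 1, 90% of effects of 2 and 100% of effects of 4, and called 2 of 28417 features without an effect. With the orientations deviating independently it called 15452 of these 28417, whereas the random block model called 1 and recovered 56% of effects of 4 and 0% of effects of 2. Only 200 features had an effect, which makes the adjusted threshold stricter than in data with many changes. The recovery rates therefore need not hold for the real data. The list test found a list shifted by 0.5 in 100% of 100 simulated runs in the first setting and 94% in the second, and called 0.68% and 0.045% of unshifted lists. Genes were simulated independently, so these rates need not hold for lists whose members vary together. Figures were drawn with matplotlib 3.10.9.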

Results

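The series compared mRNA levels in MMH cells, an immortalised line of mouse liver progenitor cells (hepatoblasts), that carried an expression vector for the homeobox transcription factor Prox1 with MMH cells that carried the empty vector. The sample titles place the cells at embryonic day 14. Each of 6 arrays measured both RNAs against each other in 2 colours. Prox1 RNA carried Cy5 on 3 arrays (replicates 1 to 3) and Cy3 on the other 3 (replicates 4 to 6). The deposited value of a feature is a ratio of both RNAs that was scaled to a standard deviation (SD) of 1 on every array. All values are therefore scores in SD units, and none is a fold change. Positive values likely mean higher with Prox1. This direction rests on the Prox1 feature at a mean score of 5.27 ± 0.14 (SD, n = 3 arrays with Prox1 in Cy5) and 6.60 with Prox1 in Cy3, rank 4 from the top of 41230 features. The labels alone do not settle it. The 3 columns with Prox1 in Cy3 held identical values in all 41230 features and were counted as 1 sample, which left 4 distinct profiles. Nothing in the labels says that the arrays came from separate cultures, so p-values measure at most the spread between arrays, which may be technical. In the model with a dye term, SE and gene p-values come from the spread of the 3 arrays with Prox1 in Cy5 alone. They leave out the difference between the orientations. That difference had an SD over features of 0.984 SD units, against a median SD of 0.139 among those 3 arrays. The number of arrays limits the precision.

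The question behind the comparison, as far as the labels show it, was which genes differ between Prox1 and empty vector cells, with the liver transcription factors Hex (Hhex) and Hnf4a, the gelatinase Mmp2 and type IV collagen as points of interest. Hnf4a, a transcription factor required for hepatocyte differentiation, fell with Prox1, with an effect of −2.96 ± 0.07 SD units (SE, 4 profiles; limma adjusted p = 1.1e-05). Hhex, a homeobox factor of early liver development, also fell, by 1.14 ± 0.10 (adjusted p = 0.00052). Mmp2, which cleaves the type IV collagen of basement membranes, rose by 5.43 ± 0.11 (adjusted p = 7.0e-06), rank 5 from the top of 28617 features. Of the type IV collagen genes, Col4a3 rose by 1.73 ± 0.07, Col4a2 by 1.05 ± 0.07 and Col4a1 by 0.62 ± 0.08, whereas Col4a5 fell by 0.56 ± 0.10. Col4a4 stood at −0.17 ± 0.07 and Col4a6 at −0.08 ± 0.07, with adjusted p = 0.10 and 0.47. The dye orientation was also treated as a random block, a choice made after seeing the data. Hnf4a, Mmp2 and Col4a3 then still passed (adjusted p = 0.00097, 0.0018 and 0.010). Hhex, Col4a1, Col4a2 and Col4a5 did not pass (adjusted p = 0.052, 0.24, 0.14 and 0.33).

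Features of the same gene did not always move together. For Prox1, 1 of 3 features carried the whole rise. The others stood at 0.41 ± 0.16 and 0.04 ± 0.12 with Prox1 in Cy5 (SD, n = 3) and at −0.29 and −0.38 with Prox1 in Cy3. The mean effect of the gene was 1.94 ± 0.07 (SE). Hnf4a had features at −4.61 ± 0.09 and −4.09 ± 0.08 (SE), both past the threshold, and another at −0.17 ± 0.09 that did not pass. Col4a3 had features at 3.18 ± 0.08, 2.08 ± 0.09 and −0.08 ± 0.08, and Col4a1 at 0.90 ± 0.09, 0.84 ± 0.09 and 0.13 ± 0.13, where the last of each gene did not pass (adjusted p = 0.50 and 0.46). Of the 42 genes named in these results that passed and had more than 1 feature, 31 passed in every feature with the sign of the gene. The other 11 were Acta2, Dcn, Itgam, Kif23, Lyz2, Nsdhl and Stab1 beside Prox1, Hnf4a, Col4a1 and Col4a3, and none had a passing feature of the opposite sign.

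**Figure D1:**
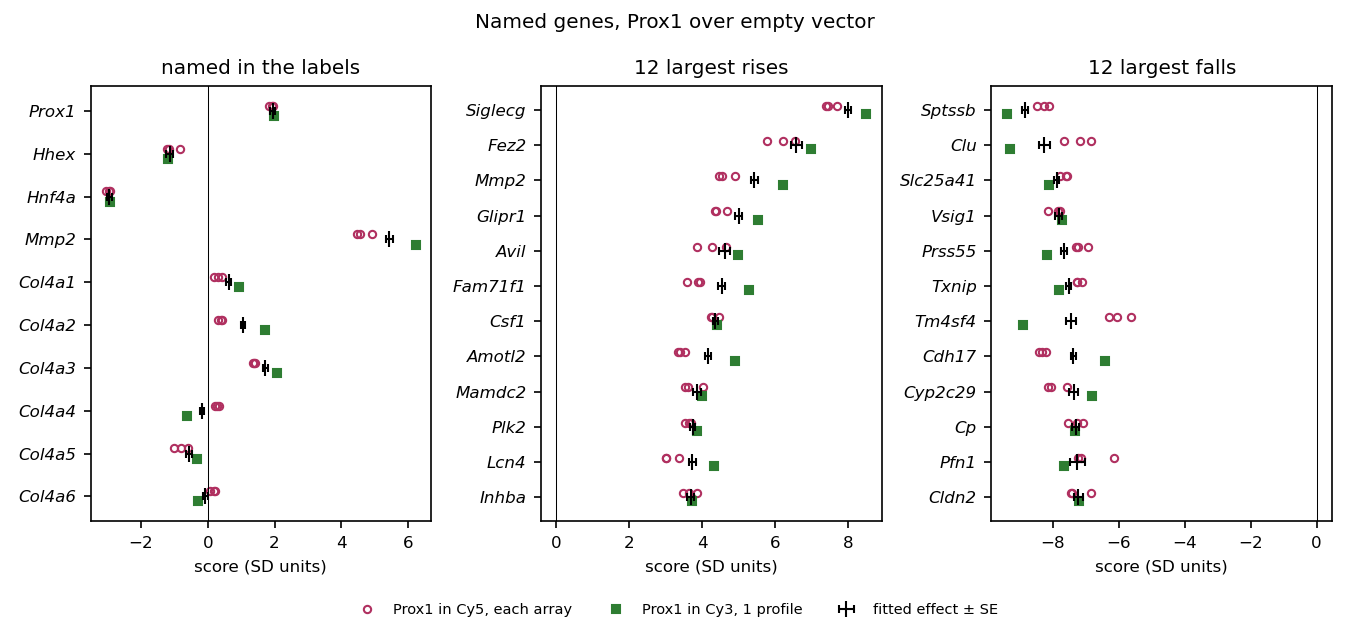
Scores of the genes named in the labels (left), the 12 largest rises (middle) and the 12 largest falls (right) in SD units, as open circles for each of the 3 arrays with Prox1 in Cy5, squares for the profile with Prox1 in Cy3, and black marks for the fitted effect ± SE. Mmp2 reaches 5.43 ± 0.11 and Hnf4a −2.96 ± 0.07; the x axes differ between panels.

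Strong falls outnumbered strong rises. The genes named here were picked among those with the same sign in all 4 profiles. Siglecg, a sialic acid-binding receptor best known from B cells, rose most, by 8.01 ± 0.09 SD units (adjusted p = 3.4e-06), followed by Fez2 at 6.58 ± 0.15, Mmp2, and Glipr1 at 5.01 ± 0.09. Avil, which encodes the actin-binding protein advillin, rose by 4.62 ± 0.16, Fam71f1 by 4.54 ± 0.10, and Csf1, which encodes macrophage colony-stimulating factor, by 4.36 ± 0.08. Amotl2 (4.16 ± 0.08), Mamdc2 (3.86 ± 0.12), the polo-like kinase gene Plk2 (3.73 ± 0.08), Lcn4 (3.72 ± 0.10) and Inhba, which encodes the βA subunit of activin (3.68 ± 0.10), completed the 12 largest rises.

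Sptssb, which encodes a small subunit of serine palmitoyltransferase, fell most, with an effect of −8.84 ± 0.09 SD units (adjusted p = 3.4e-06). Clusterin (Clu) followed at −8.27 ± 0.16, the mitochondrial carrier gene Slc25a41 at −7.88 ± 0.08, the junctional protein gene Vsig1 at −7.83 ± 0.10, the serine protease gene Prss55 at −7.68 ± 0.10 and Txnip, whose product binds thioredoxin, at −7.52 ± 0.08. The membrane protein gene Tm4sf4 (−7.45 ± 0.14), the liver-intestine cadherin Cdh17 (−7.38 ± 0.08), the cytochrome P450 gene Cyp2c29 (−7.37 ± 0.13), the plasma copper protein ceruloplasmin (Cp, −7.31 ± 0.10), the actin-binding profilin Pfn1 (−7.26 ± 0.22) and the tight junction gene Cldn2 (−7.23 ± 0.14) made up the rest. Among the 19087 genes with a symbol, 196 had an effect below −3 and 25 one above 3. All 24 genes named in these rises and falls also passed with the orientation as a random block, where the highest of their adjusted p-values was 0.0030. They were picked for size and a shared sign in the same profiles, so this is no independent support. Among these 24 genes Fam71f1 and Txnip had 2 features each and all others, Mmp2 included, only 1. No other feature of those genes can be set beside the value. Averaging over features that disagree pulls a gene towards 0, as for Prox1 (1 feature at 5.93, gene mean 1.94). The ranking therefore favours genes with 1 feature.

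Across all 28617 features tested (genes, and probes without a single symbol), 12879 (45.0%) passed an adjusted p of 0.05 in limma with a dye term. Of these 7232 were higher and 5647 lower with Prox1. With the orientation as a random block 2406 passed (967 higher, 1439 lower), all of them among the 12879. Of the 19087 genes with a symbol 5199 were higher and 4366 lower in the model with a dye term. In the random block model 740 were higher and 1166 lower. Counts of rises and falls in a list are to be read against these, since many lists lie near that background. Of the 12879 features 9636 (74.8%) had the same sign in all 4 profiles. A call favours features whose orientations share a sign, so that share does not measure agreement. Over all features tested both orientations shared a sign for 53.3%, against 49.6% for unrelated signs. The ends of the range were shared far more. Of the 286 features in the lowest 1% of each orientation 169 were in common, and of the highest 286 there were 69, against 2.86 by chance. With the orientations as 2 replicates, 3975 features had an unadjusted p under 0.05 and 0 passed in limma (smallest adjusted p = 0.088). Without a dye term 6869 passed. In data simulated with independent deviations of the orientations, the model with a dye term called 54.4% of the 28417 features without an effect, and the random block model 0.0035%.

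**Figure D2:**
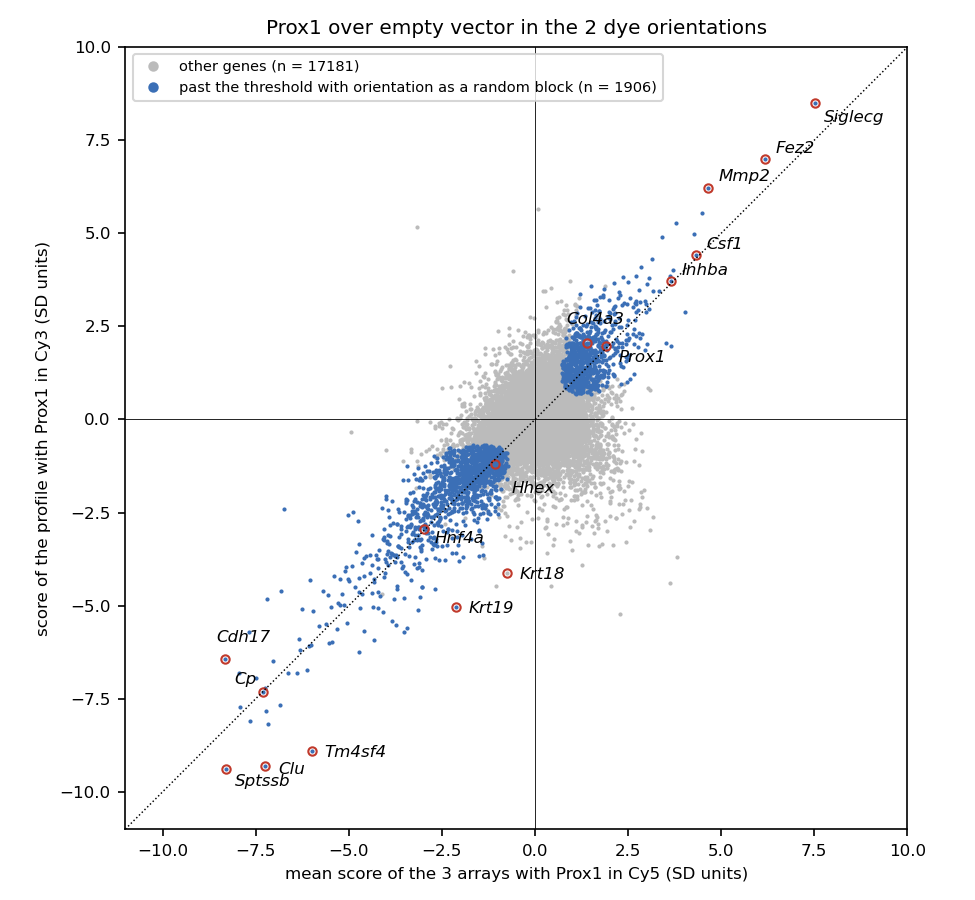
Score of each of 19087 genes in SD units as the mean of the 3 arrays with Prox1 in Cy5 (x axis) and in the profile with Prox1 in Cy3 (y axis), with equal values on the dotted line. The 1906 genes that pass with the orientation as a random block (blue) lie where both orientations share a sign. Siglecg, Fez2 and Mmp2 have the 3 largest fitted rises among the genes named in the text.

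Lists of genes that mark hepatocytes fell as groups, through part of their members. The median effect was −0.34 SD units for plasma proteins and −0.28 for bile acid and drug metabolism. It was −0.53 for fatty acid and glucose metabolism and −0.25 for liver transcription factors. In these lists 12, 14, 8 and 9 members, in that order, did not pass. Of 32 measured plasma protein genes 16 fell and 4 rose (camera adjusted p = 0.00050; adjusted p = 0.23 with an estimated correlation). Beside Cp, the effect was −5.67 ± 0.08 SD units for transferrin (Trf), −5.14 ± 0.21 for albumin (Alb) and −3.64 ± 0.16 for Itih2. Of 26 genes of bile acid and drug metabolism 12 fell and 0 rose (camera adjusted p = 0.00031; adjusted p = 0.29 with an estimated correlation). They included the glutathione transferase genes Gsta2 (−5.77 ± 0.09), Gsta1 (−5.12 ± 0.10) and Gsta4 (−4.62 ± 0.09) and the cytochrome P450 gene Cyp3a13 (−5.68 ± 0.11). Among 24 genes of fatty acid and glucose metabolism 14 fell and 2 rose, including Cpt1a, which admits fatty acids to mitochondria (−3.26 ± 0.07), the liver pyruvate kinase gene Pklr (−3.05 ± 0.13), Scd1 (−2.14 ± 0.13) and Acadl (−2.06 ± 0.08). That list had camera adjusted p = 6.2e-05 and adjusted p = 0.23 with an estimated correlation. Of 28 liver transcription factors 14 fell and 5 rose (camera adjusted p = 0.017; adjusted p = 0.49 with an estimated correlation). Beside Hnf4a, the smallest p-values there belonged to the bile acid receptor gene Nr1h4 (−2.88 ± 0.09), the nuclear receptor gene Nr1h3 (−2.67 ± 0.08) and the homeobox gene Onecut2 (−2.77 ± 0.09). In the random block model 8 plasma protein genes fell and 1 rose, 9 and 0 genes of bile acid and drug metabolism, 5 and 0 of fatty acid and glucose metabolism, and 7 and 1 liver transcription factors. On the arrays with Prox1 in Cy5 alone the transcription factor list did not pass (adjusted p = 0.073).

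Cholesterol synthesis gave the smallest p of all 23 lists. Of its 20 measured genes 17 fell and 0 rose (camera adjusted p = 4.9e-09; adjusted p = 0.23 with an estimated correlation). All 17 had the same sign in all 4 profiles, 8 of the 20 fell and 0 rose with the orientation as a random block, and the list median was −0.88 SD units. Nsdhl (−3.22 ± 0.08), Cyp51 (−3.14 ± 0.07) and Hmgcs1 (−3.0 ± 0.07) encode enzymes of the pathway, and Insig1 (−2.55 ± 0.08) encodes its sterol-dependent brake.

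Falls also outnumbered rises in the lists of cholangiocyte markers and of cell adhesion. Among 26 cholangiocyte and hepatic progenitor markers 16 fell and 4 rose (camera adjusted p = 0.00027; adjusted p = 0.23 with an estimated correlation), with Anxa13 at −4.63 ± 0.08 SD units and the keratin genes Krt8 at −3.62 ± 0.07, Krt19 at −3.58 ± 0.09 and Krt18 at −2.44 ± 0.09. Krt18 did not pass with the orientation as a random block (adjusted p = 0.12). In the list of cell adhesion and epithelial-mesenchymal transition 17 of 36 genes fell and 8 rose (camera adjusted p = 0.019; adjusted p = 0.29 with an estimated correlation). The genes with the smallest p there were junction genes: Cldn2, plakoglobin (Jup, −3.31 ± 0.08), occludin (Ocln, −2.29 ± 0.08) and β-catenin (Ctnnb1, −2.08 ± 0.09). The list also holds mesenchymal genes and transcription factors of the transition. They made up most of the 8 rises, while others of them fell or did not pass, so the fall of the list does not describe them. With the orientation as a random block, 7 of the cholangiocyte markers and 8 of the adhesion genes fell and 0 rose in either list. On the arrays with Prox1 in Cy5 alone the adhesion list did not pass (adjusted p = 0.073).

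Falls prevailed among genes of mitosis and rises in the list of cell cycle inhibitors and p53 targets. Of 29 G2 and mitosis genes 22 fell and 2 rose, with a median of −0.62 SD units (camera adjusted p = 8.9e-07; adjusted p = 0.23 with an estimated correlation). Hmmr stood at −2.59 ± 0.10, the spindle genes Kif23 at −1.76 ± 0.07 and Plk1 at −1.16 ± 0.07, and the cyclin gene Ccnb2 at −1.77 ± 0.09. Of 24 cell cycle inhibitors and p53 targets 11 rose, 3 fell and 10 did not pass (camera adjusted p = 0.027; adjusted p = 0.41 with an estimated correlation). The smallest p-values there were those of Gadd45b (3.30 ± 0.07), Mdm2, the p53 ubiquitin ligase (3.03 ± 0.07), Cdkn1a, which encodes the cyclin-dependent kinase inhibitor p21 (2.40 ± 0.07), and Gadd45g (2.31 ± 0.07). With the orientation as a random block 8 genes of G2 and mitosis fell and 0 rose, and 6 of the inhibitors and p53 targets rose and 0 fell. The latter list did not pass without a dye term (adjusted p = 0.054) or on the arrays with Prox1 in Cy5 alone (adjusted p = 0.23). The 32 genes of G1 and S phase went both ways, and the list did not pass (camera adjusted p = 0.87). Among them 13 rose, such as Fen1 (1.64 ± 0.09), and 9 fell, such as Tk1 (−3.20 ± 0.12), Rrm2 (−1.85 ± 0.09) and Tyms (−1.31 ± 0.07).

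Of 25 ribosomal protein genes 20 rose and 1 fell (camera adjusted p = 3.8e-06; adjusted p = 0.39 with an estimated correlation). Only 4 rose and 0 fell in the random block model. Rps15 (1.55 ± 0.09 SD units) and Rpl13a (1.14 ± 0.08) were among these 4 (adjusted p = 0.013 and 0.028), whereas Rpl5 (1.93 ± 0.10) and Rps3 (1.25 ± 0.07) were not (adjusted p = 0.078 and 0.27). The list's median was 1.5 with Prox1 in Cy5 and 0.44 with Prox1 in Cy3, a difference that itself passed the test between orientations. A rise of that size is therefore not shared by both.

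The remaining lists did not pass as groups, although single members moved strongly. In the list of matrix proteases and their inhibitors 8 of 30 genes rose, Mmp2 among them, and 11 fell (camera adjusted p = 0.16). The falls included basigin (Bsg, −3.79 ± 0.08 SD units), Mmp10 (−3.54 ± 0.12) and Mmp13 (−2.63 ± 0.07). Of 25 basement membrane genes 4 rose and 9 fell (camera adjusted p = 0.22), and the falls included Lamb3 (−2.32 ± 0.07), Sparc (−1.37 ± 0.07) and Npnt (−1.35 ± 0.07). In the list of growth factors and receptors of liver growth 10 of 37 rose and 13 fell (camera adjusted p = 0.16), with Fgf1 at −4.67 ± 0.15, Fgf21 at −2.59 ± 0.07, Igf2r at −2.12 ± 0.08 and Igfbp2 at −1.52 ± 0.08. The protease and growth factor lists passed with the orientation as a random block (adjusted p = 0.0098 for the proteases and 0.041 for the growth factors). Neither passed camera with an estimated correlation (adjusted p = 0.54 for each). Myc rose by 2.94 ± 0.07 and Axin1 by 1.03 ± 0.07, and Tcf7l2 fell by 1.73 ± 0.12 and Jag1 by 1.42 ± 0.07 in the list of Wnt and Notch signalling, where 6 of 35 rose and 9 fell (camera adjusted p = 0.26). Of 26 genes of endoplasmic reticulum stress and heat shock 12 rose, such as Atf3 (1.71 ± 0.10), Trib3 (1.37 ± 0.08) and Hspd1 (1.17 ± 0.07), and 10 fell, such as Xbp1 (−2.46 ± 0.09), with camera adjusted p = 0.58. Atf3 and Hspd1 did not pass with the orientation as a random block (adjusted p = 0.11 and 0.27). Of 24 hypoxia and glycolysis genes 6 rose and 10 fell (camera adjusted p = 0.17), with the glycolytic enzyme genes Pkm at −2.37 ± 0.07, Pfkl at −2.10 ± 0.07 and Aldoa at −1.40 ± 0.09 and the oxygen sensor gene Egln3 at −1.22 ± 0.07. Of these Aldoa did not pass with the orientation as a random block (adjusted p = 0.054). Of 26 interferon response genes 6 rose, such as Ifit2 (1.25 ± 0.07), Ddx58 (1.17 ± 0.07) and Gbp2 (1.06 ± 0.07), and 6 fell, such as Mx1 (−1.57 ± 0.09; camera adjusted p = 0.60). Ifit2 and Ddx58 did not pass with the orientation as a random block (adjusted p = 0.15 and 0.10). With the orientation as a random block the rises and falls were 1 and 7 for matrix proteases, 1 and 3 for basement membrane, 3 and 9 for growth factors, 2 and 3 each for Wnt and Notch signalling, for hypoxia and glycolysis and for G1 and S phase, 5 and 3 for endoplasmic reticulum stress, and 2 and 1 for the interferon response. The 10 genes from the labels, picked by the study itself and so no independent evidence of a direction, had 5 rises and 3 falls (camera adjusted p = 0.58).

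None of the lists of markers of other cell types passed as a group. Of 23 lymphatic endothelial genes, a lineage in which Prox1 is a master regulator, 3 rose, Vegfa among them (1.10 ± 0.07 SD units), and 4 fell, with Mrc1 at −2.49 ± 0.07, Ackr3 at −1.75 ± 0.18 and Angpt2 at −1.09 ± 0.08 (camera adjusted p = 0.29). Of 20 blood vessel endothelial markers 4 rose, among them Stab1 (0.73 ± 0.12), Icam2 (0.55 ± 0.11) and Esam (0.54 ± 0.09), and 1, Nos3, fell by 1.12 ± 0.11 (camera adjusted p = 0.58). Stab1 rests on 1 of 2 features (1.31 ± 0.17, against 0.15 ± 0.09). Esam stood at 2.11 with Prox1 in Cy5 and at −1.03 with Prox1 in Cy3. Of 22 stellate cell and fibroblast markers 3 rose, such as Dcn (0.74 ± 0.08), and 4 fell, with Des at −1.26 ± 0.09, Col6a1 at −1.20 ± 0.12 and Acta2 at −0.43 ± 0.08 (camera adjusted p = 0.60). The Acta2 value rests on 1 of 5 features (−2.11 ± 0.09), and that of Dcn on 1 of 2 (1.55 ± 0.10, against −0.06 ± 0.10). Of 19 blood cell markers 6 rose, among them Klf1 (0.45 ± 0.08), Lyz2 (0.39 ± 0.07) and Itgam (0.33 ± 0.07), and 1, the haemoglobin gene Hba-a1, fell by 2.21 ± 0.10 (camera adjusted p = 0.57). On the arrays with Prox1 in Cy5 alone Klf1 stood at 0.08 and Lyz2 at −0.11, and neither passed. Lyz2 and Itgam each passed in 1 of 2 features. With the orientation as a random block 0 of the blood vessel and 0 of the stellate cell and fibroblast markers passed, Nos3 and Des included (adjusted p = 0.076 and 0.067). In the lymphatic list 1 rose and 2 fell, without Ackr3 (adjusted p = 0.081), and in the blood cell list 0 rose and 1 fell. None of these lists passed with an estimated correlation.

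**Figure D3:**
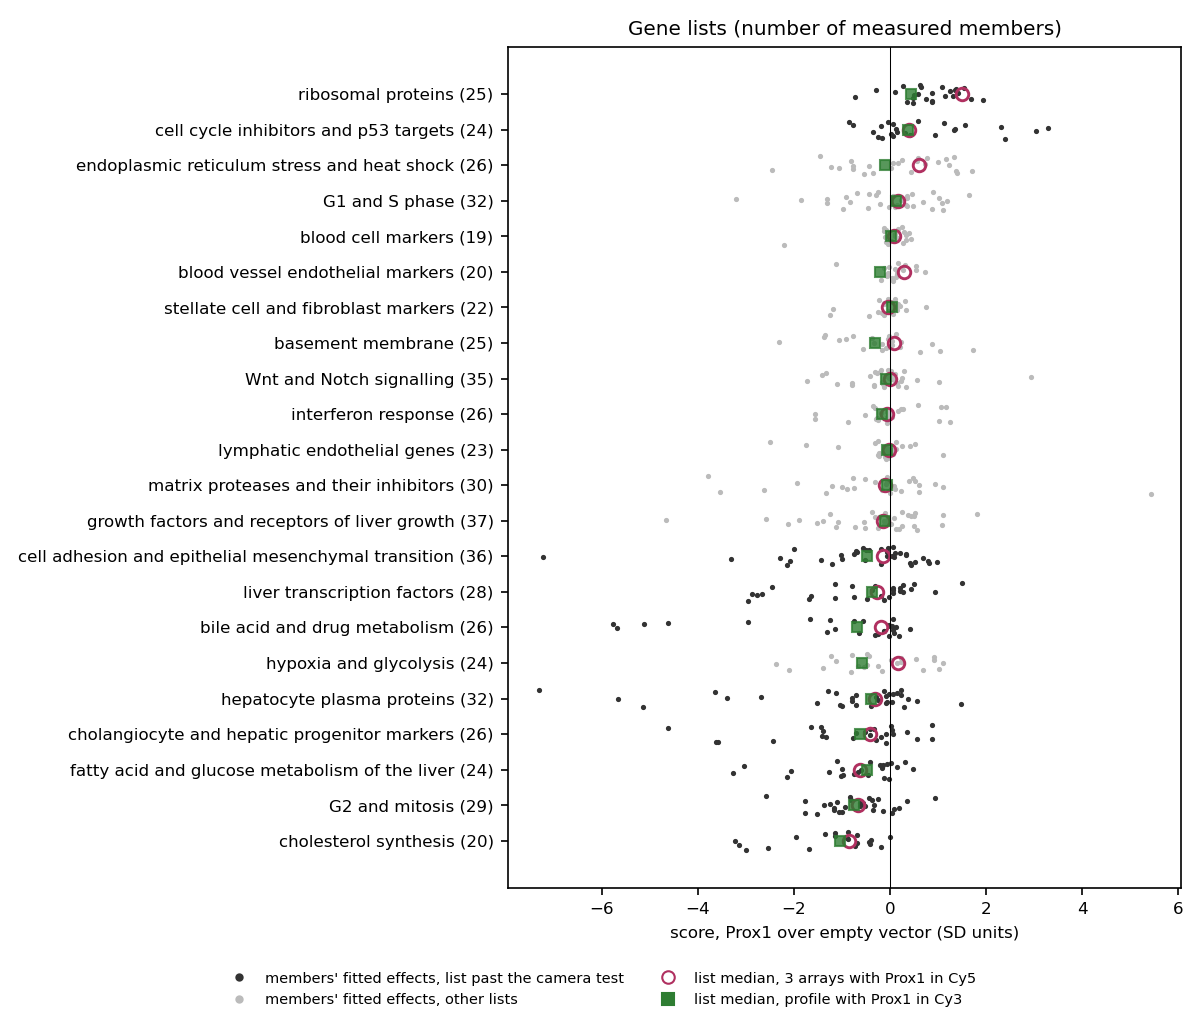
Fitted effects of the members of 22 gene lists (dots, black where the list passes the camera test), with each list's median over the 3 arrays with Prox1 in Cy5 (open circles) and in the profile with Prox1 in Cy3 (squares), in SD units. Cholesterol synthesis has the lowest median (−0.88), and ribosomal proteins show 1.5 and 0.44 in the 2 orientations.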

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

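The test of the ribosomal protein list as a measure of dye bias and that of probe pairs of the same transcript were chosen after the data were seen; the other tests in this part were set before theirs. A difference between the dye orientations was counted as such where the dye term of limma passed an adjusted p of 0.05, and a named gene also had to lie among the 5% of features with the largest absolute difference (95th percentile 1.96 SD units).

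The orientations differed in 11194 features (39.1%), and the SD of the difference over features was 0.984 SD units against a median SD of 0.139 among the 3 arrays with Prox1 in Cy5. The ribosomal protein list differed by a median of 1.13, higher with Prox1 in Cy5. Different RNA or cells behind the orientations would give a difference that probes of a gene share, and a dye bias or spot noise of the probe would not. Over 4333 pairs of probes with different transcript accessions the difference correlated at r = 0.036 (95% bootstrap interval 0.0056 to 0.065), but the mean ratio itself reached only 0.282 (0.239 to 0.324) there. Over 5673 pairs with the same accession the difference correlated at 0.170 (0.144 to 0.197) and the mean ratio at 0.595 (0.565 to 0.624), and the probes of Rps3 stood alike at 2.51 and 2.73 with Prox1 in Cy5 and at −0.15 and −0.07 with Prox1 in Cy3. Part of the difference is thus shared by probes of a transcript, which can share sequence, and both explanations stay open. An intensity-dependent dye bias stays open: the ribosomal difference of 1.13 lies outside the range of 95% of random lists (−0.31 to 0.33), but that difference raised the question in the first place and so does not decide it. No other list passed the camera test of the difference. The hypoxia and glycolysis list (median difference 0.50, adjusted p = 0.36) and the blood vessel endothelial list (0.37, adjusted p = 0.29) leaned the same way. The growth factor list leaned the other way (−0.34, adjusted p = 0.31). A real difference in ribosomal transcripts between the RNAs of both orientations stays open as well.

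Single named genes also differed between the orientations. Clu was lower with Prox1 in Cy3 than in Cy5 by 2.06 SD units, Tm4sf4 by 2.91, Krt19 by 2.92 and Krt18 by 3.37, with all 4 below 0 in both. Rpl5 was higher with Prox1 in Cy5 by 2.29. Rps3, Hspd1 and Esam were higher there by 2.73, 2.51 and 3.14 and below 0 with Prox1 in Cy3 (−0.11, −0.08 and −1.03), so their rise was not shared. The difference for Atf3 was −2.11, with both orientations above 0.

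Strong falls outnumbered strong rises, with 196 genes below −3 SD units and 25 above 3, a ratio of 7.84. The single arrays differed by orientation, with 572 to 589 features below −3 and 102 to 128 above 3 with Prox1 in Cy5, against 470 and 244 with Prox1 in Cy3. Centring does not account for the fitted asymmetry, since the ratio was 8.08 with each column centred on its median. Genes of the plasma protein, bile acid and drug, and fatty acid and glucose lists were over-represented below −3, with 11 of 82 there (odds ratio 15.8, 95% interval 7.40 to 30.6, two-sided Fisher's exact p = 7.5e-10). These 11 are few of the 196, so most of the asymmetry lies in genes outside these lists. A loss of hepatocyte-expressed genes may be a part of the asymmetry as a hypothesis. This rests on the likely direction. With the sign turned there would be 196 strong rises and 25 strong falls, with the liver genes over-represented among the rises. Saturation or a floor of the brightness could not be examined without intensities.

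Turning the sign of profiles gives 8 patterns, and the real one called 12879 features, with 1 of the 8 as large. The highest other pattern, which turns the profile with Prox1 in Cy3 and so follows the dye, called 11194. With 8 patterns the share cannot fall below 0.05.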

How the results depend on the processing

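The random block, the orientations as 2 replicates, the identical columns as 3 arrays and each orientation by itself were chosen after seeing the data. Without a dye term 6869 features passed (3423 higher, 3446 lower), with the random block 2406 (967 and 1439), with the identical columns as 3 arrays 20329 (11288 and 9041), and with the orientations as 2 replicates 0 (0 and 0; 3975 at an unadjusted p under 0.05). Without a dye term the difference between the orientations enters the residual spread, and the effect becomes the plain mean of the 4 profiles. How much each adds to the first shift was not tested. With the orientations as 2 replicates the fit has 1 residual degree of freedom before moderation, and the difference between the orientations enters its residual spread. How much each adds to the count of 0 was not tested. In both simulated settings that fit recovered 0% of effects of 4 SD units, so the count does not show that effects are absent. Centring, scaling, quantile normalization, array weights, robust moderation, the stricter threshold and the Cy5 arrays alone gave 8992 to 16781. With each probe by itself 18604 passed, out of 41230 tested. Leaving out 1 array with Prox1 in Cy5 gave 11386 to 12357. Lists called were 10, but 0 with an estimated correlation and 19 with fry, which does not compare a list with other genes and turned the direction of the interferon response list (median −0.054). The list of cell cycle inhibitors lost its call without a dye term (adjusted p = 0.054), with the identical columns as 3 arrays (0.062) and on the Cy5 arrays alone (0.23). In all, 3 lists lost their call on the Cy5 arrays alone and 1 gained one. On the Cy5 arrays alone Col4a4 turned to 0.27 and Lyz2 to −0.11. Of 116 genes named by the rule 114 passed and 90 also did with the random block (15 and 13 of the 17 chosen later). Without a dye term 16 named genes lost their call: Acta2, Atf3, Col4a1, Col4a2, Ddx58, Esam, Hspd1, Icam2, Ifit2, Itgam, Klf1, Krt18, Lyz2, Neurod1, Rps3 and Vars. None changed call under centring or scaling; Ptf1a gained a call with quantile normalization, array weights or robust moderation, and Neurod1 lost its call without replicate 1. In the profile with Prox1 in Cy3 alone all 10 called lists kept the sign of their median. For 10 of 23 lists the median there lay further from the fitted one than the SD of the 2 orientation medians. This yardstick is widest where the orientations differ most, so the count does not measure dependence on the orientation. Leaving out replicate 4, 5 or 6 changes nothing, since their columns are identical, and filters on missing values coincide. No paired analysis was possible because the orientations share no replicate numbers. A fold threshold was not run. Signal over background is unknown.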

Other observations

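The tests in this part were chosen after the strongest rises and falls had been seen, and members already seen there were left out of each test and of the counts of lists.

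Genes of intestine and stomach stood among the falls beside Cdh17 and Vsig1. Of 33 measured genes in a list of gut, stomach and pancreas genes, without 8 others already seen among the strongest falls, 12 fell and 4 rose (8 and 1 with the orientation as a random block). The falls included the intestinal fatty acid-binding protein gene Fabp2 (−4.08 ± 0.07 SD units), the trefoil factor genes Tff3 (−2.37 ± 0.12) and Tff1 (−2.09 ± 0.13), the keratin gene Krt20 (−2.92 ± 0.09), the guanylin gene Guca2a (−2.02 ± 0.09) and villin (Vil1, −1.82 ± 0.08), while Mttp rose by 2.14 ± 0.12 and the endocrine factor gene Neurod1 by 0.32 ± 0.09 (adjusted p = 0.030, but 0.061 without replicate 1 of Prox1 in Cy5 and 0.59 with the random block). These genes were chosen after their values were seen. As a hypothesis, Prox1 may lower a wider set of gut genes: the 33 lay below other genes (camera p = 0.0026, with p = 0.11 with an estimated correlation). The pancreatic factors Pdx1 (−0.19 ± 0.07) and Ptf1a (0.27 ± 0.08) did not pass. Gut and pancreatic members were not tested against each other.

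Rises prevailed among genes of ribosome biogenesis. Of 39 measured ribosome biogenesis genes 32 rose and 0 fell (5 and 0 with the orientation as a random block), with medians of 0.78 SD units with Prox1 in Cy5 and 0.81 with Prox1 in Cy3, and the 5 included Wdr12 (1.99 ± 0.09), Dkc1 (1.48 ± 0.09), Nop10 (1.45 ± 0.09) and Bysl (1.09 ± 0.08). Of 17 aminoacyl-tRNA synthetase genes 10 rose and 3 fell (3 and 0 with the random block), with Yars (1.84 ± 0.08) and Eprs (1.81 ± 0.07) rising and Vars (−0.45 ± 0.07) falling. A joint rise of ribosome biogenesis is a hypothesis: 29 of 39 such genes were above 0 in both orientations (one-sided Fisher's exact p = 9.8e-09), against 29.6% of all genes. The synthetases, which charge tRNAs, had 9 of 17 (one-sided Fisher's exact p = 0.037), so the share of 67.9% (38 of 56) over both lists rests mostly on the biogenesis genes. Genes of a list are not independent, so these p-values are too small by an unknown amount, and the camera p with an estimated correlation was 0.021 for ribosome biogenesis and 0.21 for the synthetases.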
